A study of Mus musculus with 6 samples.

How the data were processed

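Hippocampal RNA of 14-month-old male C57BL/6 mice was measured in 6 libraries, 3 from mice given dihydrotestosterone (DHT) and 3 from mice given corn oil, each for 14 days. Groups came from the treatment labels, and the tissue is named as the labels give it. The labels give no batch and no shared replicate numbers (title numbers 19, 26 and 27 for DHT, 2, 3 and 7 for oil), and replicates are numbered 1 to 3 in each group for naming only.

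Back-splice junction read counts per circRNA were deposited by the authors, with only circRNAs of at least 2 reads listed in a library, so an unlisted circRNA counts as 0 here and can hold 1 read. The same lists carry counts of linear reads at each listed circRNA, for which the counting method is not given in the sources used here. The lists also carry a deposited score per circRNA, which is SRPBM (junction reads per G, giga, mapped reads) rounded down to whole numbers by the authors, per the labels' protocols and the values. The score was used only to work out the mapped reads of each library, from 143 to 177 M (mega), which reproduced all listed scores (100%). FPKM values were deposited by the authors for each of 315379 first-exon, last-exon and splicing events of assembled loci, per the file headers, and not for genes. Submitters' processing notes list bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1 and BWA without roles. The circRNA caller, the assembler and the tool that gave FPKM are not given in the sources used here, and the series' design text names DESeq2 1.6.3 for its own comparison. The notes also name the build mm9, but 99.5% of 11398 circRNAs with a host gene in the reference table lay within the GRCm38 bounds of that gene, so coordinates are treated as GRCm38. Overlapping and antisense genes, and near-identical copies, cannot be told apart in such files.

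A gene value was computed in each library as the larger of the sum of first-exon events and the sum of last-exon events of a locus, added over loci that share a gene identifier. Of 32348 identifiers, 99.7% matched a symbol. The plan written beforehand had assumed gene or transcript FPKM, and this definition was chosen after the files and the spread of replicates were seen but before any comparison of groups. In 6.66% of 10188 loci checked, some single event exceeded both sums, so the definition can miss transcripts. An exact 0 in FPKM can be a failed estimate, since genes used by every cell are also listed at 0 in places. Such genes are given library by library.

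Genes with a mean of at least 0.5 FPKM (11368) were tested on log2(FPKM + 0.5) with limma 3.58.1 (empirical Bayes with a trend, R 4.3.3), and fold changes are on that scale, which understates those of low genes. circRNAs with at least 20 junction reads over the 6 libraries (2524) were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, all junction reads as library size) on the counts as deposited, and with DESeq2 1.42.0 as an alternative. Adjusted p is Benjamini-Hochberg's, with a threshold of 0.05. circRNA levels are reads per M junction reads after TMM. The threshold of the series, an unadjusted p under 0.05 and at least 2-fold, was applied to the same fits. Gene lists, 42 of them fixed before the data were examined and covering steroid response, inflammation, cell types, brain regions, synapses and basic cell functions, were tested with limma's camera (preset correlation 0.01) where at least 4 members were measured, and again with an estimated correlation and with fry. circRNAs were grouped by host gene and tested in the same way. Single values were compared with exact two-sided permutation tests, and correlations with 100000 permutations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

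Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.29 to 2.96), so no library was counted as a repeat of another. A fold against a group with no listed reads is a bound against a floor of 3 reads per library, which covers counting error only.

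The methods were tested on simulated data made from the means and depths of these libraries. Every simulated circRNA was given the same spread (biological coefficient of variation 0.414), and every linear locus the same (0.0897), while each gene kept its own. For circRNAs, edgeR recovered 0 of 67 changed by 1.5-fold, 1 of 67 by 2-fold and 4 of 66 by 3-fold, so with that spread most changes of that size would be missed. The circRNAs with at least 60 reads had a coefficient of 0.265, so recovery may be higher for abundant circles. For genes, limma recovered 10 of 67, 37 of 67 and 53 of 66, with 3 false calls among 103. For linear reads edgeR recovered 53 of 67, 65 of 67 and 65 of 66, with 8 false calls among 191, which may be too favourable for loci that vary more.

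Named genes were fixed by rule before the data were examined: Nufip2 and Y-linked or X-inactivation genes, then up to 10 in each direction with the largest change among genes that passed without overlap, filled to 8 by the smallest p where fewer passed, and up to 4 members with the smallest p of each list described. Unnamed gene models were counted only. Some genes that this rule takes are not reported here, though they stayed in every test. circRNAs followed the same rule with 8 in each direction. The most abundant circRNAs, the glial and regional marker levels, the linear reads, the scaffold locus, the intergenic share without it and the Nup98 events were added after the data were seen.

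Alternatives covered normalization, tool, filters on low values, pseudocount, leaving out each library, and, added after the data were seen, other gene values, circRNAs listed in all 6 libraries, robust dispersions, 1 circRNA per host gene and the removal of DHT library 2 and oil library 3 together. For total abundance, circRNAs listed in all 6 libraries had been planned, as had 1 circRNA per host gene for the correlation of circular and linear changes. Lists for choroid plexus, ependyma, neurogenesis and mitochondrial transcripts had under 4 measured members (3, 2, 3 and 0) and were not tested. Lists of excitatory, inhibitory, oligodendrocyte and astrocyte host genes had 3, 0, 1 and 0 circRNAs.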

Results

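RNA from the hippocampus of 14-month-old male C57BL/6 mice was sequenced after 14 daily injections under the skin of dihydrotestosterone (DHT), an androgen that is not converted to oestrogen by aromatase, or of corn oil, its vehicle. There were 6 libraries, 3 from DHT mice and 3 from oil mice. The tissue is named as the labels give it. In these libraries 8 of 9 striatal marker genes had a mean over 5 FPKM, as described under other observations. The sample descriptions also use the words testosterone group for the DHT libraries. The libraries were read for circular RNAs (circRNAs), closed rings made when a downstream splice site joins an upstream one, and for exon and splicing events of the assembled transcripts. The DHT libraries held 55325, 49815 and 43512 back-splice junction reads and the oil libraries 48212, 45803 and 43573, out of 177, 167, 143, 159, 154 and 156 M (mega) mapped reads in the same order. Across the libraries 11895 circRNAs were listed, of which 10413 were exonic, 1132 intronic and 350 intergenic. Of these, 1581 were listed in all 6 libraries and 5686 in 1 library only. The labels do not say whether each library is 1 animal, so p-values measure the spread between these libraries, which may be partly technical.

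The first comparison asked whether DHT altered the total amount or the variety of circRNA in the hippocampus. DHT libraries held 305 ± 6.79 junction reads per M mapped reads (SD, n = 3) against 293 ± 13.0 in oil libraries (SD, n = 3), a difference of 3.93% that was within the spread (exact permutation test, two-sided, p = 0.3). They listed 5135 ± 365 circRNAs against 4682 ± 200 (SD, n = 3 per group, exact permutation p = 0.2). Thinned to the smallest total of 43512 junction reads, the numbers were 4840 ± 89.0 and 4580 ± 99.5, with all 3 DHT libraries above all 3 oil libraries (exact permutation p = 0.1). Intergenic circRNAs took 3.64 ± 0.938% of the junction reads in DHT libraries and 6.55 ± 1.11% in oil libraries, again without overlap (exact permutation p = 0.1). This gap came from 1 place, the unplaced scaffold JH584304.1 described below: without its circles the shares were 1.67 ± 0.289% and 1.65 ± 0.142% (exact permutation p = 0.9), a comparison chosen after the data were seen. For 3 libraries against 3, 0.1 is the smallest p these tests can give.

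The second comparison, the one the series describes, asked which circRNAs differ after DHT. The most abundant circRNA in these libraries was an exonic circle hosted by Cdr1os on chromosome X (61183248 to 61186174). It stood at 79477 ± 11150 reads per M junction reads in DHT libraries and 75982 ± 13198 in oil libraries (SD, n = 3 per group here and below). Its log2 fold change was 0.06 (SE 0.13). Circles of Tulp4 (chromosome 17, 6137211 to 6139156) were at 14104 ± 386 against 11819 ± 567, of Rnf169 at 5298 ± 267 against 6211 ± 593, and of Ankib1 at 5760 ± 417 against 5609 ± 308. Circles of Unc79, a component of the NALCN sodium leak channel complex, were at 5379 ± 1081 against 5373 ± 886, and those of the cadherin Fat3 at 5282 ± 382 against 4483 ± 397. None of the 2524 circRNAs with at least 20 junction reads passed an adjusted p of 0.05: edgeR called 0, with 79 at an unadjusted p under 0.05 where 126.2 would be given by chance, and DESeq2 called 0 with 73. Between the groups 279 circRNAs (11.1%) did not overlap, where chance gives 10%.

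The circRNAs with the smallest p on the higher side, none of which passed, were mostly rare. A circle of Cep164 (chromosome 9, 45794052 to 45794429), which encodes a protein of the ciliary base, had 10, 8 and 10 reads in DHT libraries and was not listed in oil libraries, so it was at least 2.87-fold higher against a floor of 3 reads per library. A circle of the neuronal RNA-binding protein gene Elavl3 (chromosome 9, 22036312 to 22036857) had 5, 11 and 7 reads against none listed, at least 2.38-fold higher. Circles of the transcription factor gene Klf12 (11, 6 and 3 reads) and of an intergenic stretch of chromosome 2 (143420619 to 143486483; 8, 6 and 7 reads) were likewise listed in DHT libraries only among these 6, at least 1.99-fold and 2.15-fold higher. Circles of Tmcc1 were at 688 ± 102 against 295 ± 125 reads per M junction reads (log2 fold change 1.22, SE 0.35), of the SNARE gene Snap47 at 215 ± 64.2 against 21.7 ± 37.6, and of the chromatin gene Baz2b at 210 ± 94.9 against 35.0 ± 31.6. The Ppp1r9a circle (chromosome 6, 5045936 to 5083106) had 735 reads in DHT library 1 and was listed in no other library. All 8 had an edgeR adjusted p of 0.996.

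On the lower side, 2 overlapping circles without a host gene on the minus strand of the unplaced scaffold JH584304.1 came first. The one from 25369 to 59773 had 37, 142 and 85 reads in DHT libraries and 249, 217 and 398 in oil libraries (log2 fold change -1.83, SE 0.40), and the one from 25369 to 60857 had 374, 1268 and 929 against 1612, 1852 and 2331 (log2 fold change -1.28, SE 0.34). Circles of Thrb, the thyroid hormone receptor beta gene, were at 134 ± 5.90 against 356 ± 31.9 reads per M junction reads (chromosome 14, 17925596 to 17963321; log2 fold change -1.39, SE 0.42). Those of Arhgap10 were at 126 ± 58.0 against 369 ± 74.2, those of the ceramide synthase gene Cers6 at 94.0 ± 6.61 against 284 ± 39.3, and those of Zfp644 at 286 ± 58.2 against 615 ± 194. A circle of Phf3 was at 55.0 ± 61.3 against 274 ± 82.8, and a circle of the cohesin release gene Wapl had 6, 3 and 11 reads in oil libraries and none listed in DHT libraries, at least 2.45-fold lower. These 8 also had an edgeR adjusted p of 0.996. When only the 1581 circRNAs listed in all 6 libraries were tested, a choice made after the data were seen, edgeR called both scaffold circles (adjusted p = 2.80e-16 and 1.23e-11) while DESeq2 called 0 of the same 1581. In that fit edgeR gave every circRNA the shared variance.

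**Figure D1:**
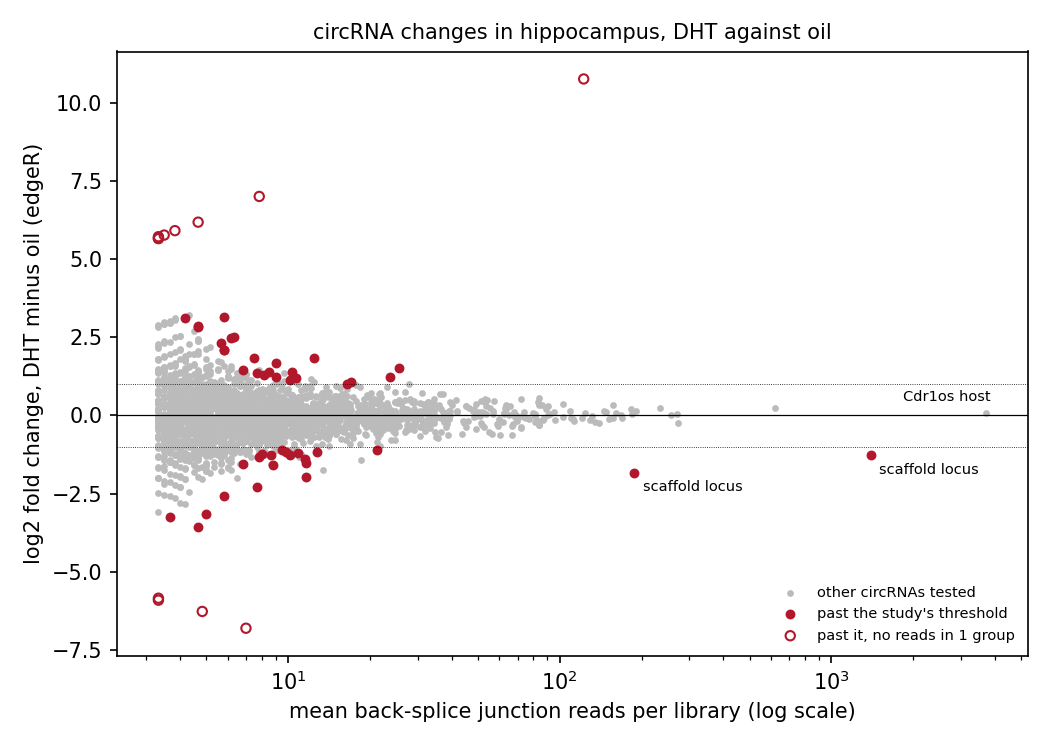
Fitted log2 fold change (DHT minus oil, edgeR) of each of the 2524 tested circRNAs against its mean back-splice junction reads per library on a log scale. Filled red points passed an unadjusted p of 0.05 and a 2-fold change, hollow red points did so with no reads listed in 1 group, where the fitted value depends on the prior count, and dotted lines mark 2-fold. None passed an adjusted p of 0.05.

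At the threshold that the series describes, an unadjusted p under 0.05 and a change of at least 2-fold, edgeR counted 57 circRNAs, 32 higher and 25 lower in DHT libraries. This balance turned with the libraries used, to 13 higher and 31 lower without DHT library 1 and 31 and 36 without DHT library 2, against 53 and 28 without oil library 2. For 12 of the 57, 1 group had no listed reads. DESeq2 counted 57 as well, 38 higher and 19 lower, and 38 circRNAs were in both counts. No correction for many tests is part of this threshold, and 126.2 of the 2524 circRNAs would be under an unadjusted p of 0.05 by chance before the fold is asked for.

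The circRNA that the series title names, mmu_circ_0001442, is not analysed here, since the lists carry no such names and no coordinates for it are at hand. The mRNA target named with it, Nufip2, which encodes an RNA-binding partner of FMRP, had a gene value of 6.63 ± 0.585 FPKM in DHT libraries and 5.48 ± 1.30 in oil libraries (SD, n = 3 per group; log2 fold change 0.27, SE 0.18, limma adjusted p = 0.721). A circle hosted by Nufip2 (chromosome 11, 77691542 to 77693254), not known to be the named one, had 8 and 12 reads in DHT libraries 1 and 2, none listed in DHT library 3, and 6, 3 and 4 in oil libraries. The Y-linked genes Kdm5d and Uty were present in all 6 libraries, as male tissue requires, at 0.661 ± 0.148 against 0.637 ± 0.165 and 3.17 ± 0.288 against 3.90 ± 1.02 FPKM.

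Most tested circRNAs of genes for the postsynaptic density were higher in DHT libraries, with a group call that depended on the test used. Circles of the same host gene are not independent. Of 25 tested circRNAs from 9 such host genes, 18 were higher and 7 lower, with a median log2 fold change of 0.31, and the group passed camera's test with a preset correlation (adjusted p = 0.0303). With an estimated correlation the adjusted p = 0.269 and with limma's fry 0.174, so the call was lost in both. Circles of the scaffold gene Dlgap1 (chromosome 17, 70761075 to 70787209) were at 2061 ± 308 against 1404 ± 345 reads per M junction reads (SD, n = 3 per group), those of Shank3 (chromosome 15, 89547626 to 89549882) at 637 ± 99.5 against 340 ± 278, and those of Homer1 (chromosome 13, 93386345 to 93393108) at 322 ± 137 against 176 ± 34.4. The Shank3 circle had 8, 9 and 28 reads in oil libraries, and its log2 fold change ran from 0.61 to 1.82 on leaving out 1 library. A second Homer1 circle (chromosome 13, 93341756 to 93356079) was at 2007 ± 168 against 1576 ± 189. No member passed by itself, neither over all circRNAs (0) nor adjusted over the list alone (0), although 1 had an unadjusted p under 0.05. Circles of presynaptic host genes (36, 20 of them higher, camera adjusted p = 0.559) and of genes known as frequent circRNA hosts (73, 39 higher, adjusted p = 0.559) did not pass limma's camera. The postsynaptic call of limma's camera was also lost without DHT library 2 (adjusted p = 0.111), without oil library 2 (0.217), without DHT library 2 and oil library 3 together (0.0570), with at least 6 reads (0.202) and with 1 circRNA per host gene (0.0789). In that last setting the 6 presynaptic circRNAs passed (0.0224).

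The third comparison asked which genes differ in the linear transcriptome. Gene values are sums of first-exon or last-exon FPKM, and 2 of 11368 genes passed limma's test at an adjusted p of 0.05. Nup98, which encodes a nuclear pore protein, was lower in DHT libraries at 0.721 ± 0.0853 against 4.40 ± 0.494 FPKM (SD, n = 3 per group; 4.01-fold on the scale of FPKM + 0.5, log2 SE 0.13, limma adjusted p = 0.0163). A retained-intron pair of the same locus (chromosome 7, 102124394 to 102125103) held 3.83 ± 0.433 against 4.44 ± 0.388 FPKM, so the call rests on which exons carried the signal. The other was the unnamed model Gm22543, named here after its values were seen, at 1.23, 1.20 and 1.22 FPKM in DHT libraries and listed at 0 in oil libraries (adjusted p = 0.0380). At an unadjusted p under 0.05 there were 834 genes, where chance gives 568.4, of which 658 were higher and 176 lower in DHT libraries. With each library centred on its median log value these became 685, 359 higher and 326 lower, and the share of all genes that were higher moved from 63.6% to 51.4%. Without centring, groups did not overlap for 1720 genes (15.1%), where chance gives 10%. A shift of whole libraries can raise this share, and it was not computed with centring. Gene values summed to 94871, 96063 and 95613 FPKM in DHT libraries and to 89596, 87300 and 87148 in oil libraries. Neither gene was called with first-exon sums only, last-exon sums only or the fullest event of each locus, which called 0 genes each, with 825, 627 and 844 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 4 calls, 0 of them without DHT library 1, DHT library 3, oil library 1 or oil library 2, and 4 without DHT library 2. The log2 fold change of Nup98 stayed at -2.08 to -1.94 with 1 library left out, so only the adjusted p was lost there.

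The genes with the smallest p on the higher side, none past the threshold, follow. Inf2, a formin that builds and severs actin filaments, stood at 29.1 ± 0.502 against 15.4 ± 2.21 FPKM (SD, n = 3 per group; log2 fold change 0.91, SE 0.13, limma adjusted p = 0.529), and the membrane-bending gene Fnbp1 at 19.5 ± 2.25 against 9.63 ± 1.49. Disc1, a scaffold gene of neuronal development, was at 1.69 ± 0.0455 against 0.428 ± 0.213, the heat shock gene Hspa2 at 5.63 ± 0.992 against 1.89 ± 0.671, the actin regulator Nckipsd at 8.20 ± 0.476 against 5.35 ± 0.155. The centrosomal gene Cep170b was at 39.2 ± 7.13 against 21.0 ± 2.10. Slc35c1, the GDP-fucose transporter gene, had 2.06, 2.19 and 0.991 FPKM in DHT libraries and 0.277, 0.143 and 0 in oil libraries. The cell cycle inhibitor Cdkn2d had 5.04, 1.24 and 4.11 against 0.152, 0.172 and 0. On the lower side was the ciliary GTPase gene Arl3 at 5.38 ± 0.690 against 11.8 ± 1.24 (log2 fold change -1.06, SE 0.13, limma adjusted p = 0.397). Svil was at 0.980 ± 0.205 against 2.19 ± 0.0933, and the proteasomal deubiquitinase gene Usp14 at 8.72 ± 0.674 against 13.1 ± 0.689. Rps27a, a fusion of ubiquitin and a ribosomal protein, was at 8.71 ± 1.13 against 14.2 ± 1.05. The ATP synthase subunit Atp5e was at 1.19 ± 0.278 against 4.94 ± 2.14, Rgs19 at 1.73 ± 0.344 against 3.14 ± 0.0389 and Mir7648 at 2.13 ± 0.344 against 3.79 ± 0.161.

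Steroid and inflammatory gene groups, the ones closest to the question of the series, gave no call. Beside the counts of higher genes here and in later paragraphs, 63.6% of all tested genes were higher, or 51.4% with centred libraries. With centred libraries the median log2 fold change of the androgen response genes was 0.042. Of 17 measured androgen response genes 11 were higher and 6 lower (camera adjusted p = 0.815), with Ndrg1 at 13.1 ± 0.167 against 11.1 ± 0.812 FPKM and Pmepa1 at 3.62 ± 0.424 against 3.03 ± 0.131 (SD, n = 3 per group). All 4 measured steroid receptor genes were lower (adjusted p = 0.510), among them the glucocorticoid receptor gene Nr3c1 at 7.00 ± 0.547 against 7.74 ± 0.822 and the progesterone receptor gene Pgr at 3.36 ± 0.548 against 3.88 ± 0.838. Of 9 microglial genes 6 were higher and 3 lower (adjusted p = 0.909), their median log2 fold change being 0.10, their mean -0.00431 and the direction of the test, which sets them against the other genes, lower. The microglial gene Fcrls was at 2.83 ± 0.260 against 2.47 ± 0.0252 and Aif1, which encodes the actin-binding protein IBA1, at 0.955 ± 0.348 against 0.633 ± 0.144. In this list 1 gene passed when adjusted over the list alone and 0 over all genes. In the interferon list 6 of 10 genes were higher (adjusted p = 0.909), and Ifi27, at 4.01 ± 0.980 against 1.99 ± 0.310, was the 1 gene passing when adjusted over the list alone, with Rtp4 at 0.902 ± 0.255 against 0.429 ± 0.0138. Of 10 cytokine and NF-kB genes 7 were higher (adjusted p = 0.909), with the prostaglandin synthase gene Ptgs2 at 1.59 ± 0.479 against 0.929 ± 0.129 and the subunit gene Rela at 3.52 ± 0.108 against 3.18 ± 0.401. Of 7 complement genes 5 were higher (adjusted p = 0.909), with C1qb at 23.2 ± 3.81 against 18.0 ± 3.65. For the androgen, steroid receptor, cytokine and complement lists 0 genes passed when adjusted over the list alone.

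Some glial reaction genes were highest in 1 library of each group, DHT library 2 and oil library 3, by amounts that differ from gene to gene. The acute-phase gene Lcn2 was at 3.15, 3.97 and 1.88 FPKM in DHT libraries and at 0.338, 0.267 and 10.5 in oil libraries, and Serpina3n at 3.66, 5.88 and 3.42 against 2.95, 2.79 and 9.81. C4b was at 4.24, 12.8 and 5.80 against 3.91, 4.60 and 14.6, and the intermediate filament gene Gfap at 17.6, 39.4 and 22.8 against 16.8, 14.7 and 35.9. Others did not follow in the DHT group, such as the cytokine receptor gene Osmr at 1.03, 0.898 and 1.22 against 0.201, 0.433 and 1.94. Of 12 reactive astrocyte genes 7 were higher and 5 lower over all libraries (camera adjusted p = 0.909, direction of the test lower although the median log2 fold change was 0.08), and of 15 glucocorticoid response genes 11 were higher (adjusted p = 0.909), such as the metallothionein gene Mt1 at 100.3 ± 11.3 against 83.0 ± 5.76 (SD, n = 3 per group). Without oil library 3 both lists passed as higher in DHT libraries (limma's camera, adjusted p = 0.0113 and 0.00103). With an estimated correlation they did not (adjusted p = 0.841 for both). Oil library 3 had the highest value of Lcn2, which both lists hold, so its removal favours this direction and is no test of either list. Of the haemoglobin genes, whose transcripts blood carries, Hba-a2 was at 282, 589 and 238 FPKM in DHT libraries against 148, 159 and 84.0. Hbb-bs, at 147, 311 and 53.1 against 71.2, 124 and 66.5, and Hbb-bt, at 81.2, 134 and 52.8 against 38.6, 70.8 and 40.2, overlapped between the groups. Of 6 blood genes 4 were higher (adjusted p = 0.715), and Hba-a2 was the 1 gene passing when adjusted over the list alone.

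Neuronal groups went both ways and none passed. Of 11 immediate-early genes, which respond to neuronal activity, 10 were higher (camera adjusted p = 0.400), and the nuclear receptor gene Nr4a1, at 7.02 ± 0.417 against 4.84 ± 0.361 FPKM (SD, n = 3 per group), was the 1 gene passing when adjusted over the list alone. Fosl2 was at 2.75 ± 0.594 against 1.90 ± 0.181, Egr1 at 16.3 ± 2.50 against 13.0 ± 1.91 and Nr4a2 at 3.23 ± 0.123 against 2.73 ± 0.249. Without DHT library 2 the immediate-early list passed as higher (limma's camera, adjusted p = 0.0122), but not with an estimated correlation (adjusted p = 0.912). Of 15 presynaptic genes 10 were higher (adjusted p = 0.600), among them the SNARE gene Stx1a at 17.9 ± 4.14 against 10.2 ± 3.03. The synaptic vesicle gene Syn1 was at 67.6 ± 3.89 against 56.9 ± 1.48, Syp at 132 ± 2.86 against 113 ± 3.91 and Vamp2 at 143 ± 6.99 against 123 ± 1.76. Of 13 postsynaptic genes 9 were higher (adjusted p = 0.819), with Dlgap4 at 33.8 ± 3.26 against 27.7 ± 0.670 and Nlgn2, an adhesion gene of inhibitory synapses, at 24.0 ± 1.51 against 20.1 ± 1.79. Beside these counts, 63.6% of all genes were higher, and with centred libraries the median log2 fold change of the postsynaptic genes was 0.013. Of 8 excitatory neuron genes 5 were higher but the direction of limma's camera was lower (adjusted p = 0.909), with the vesicular glutamate transporter gene Slc17a7 at 69.5 ± 19.7 against 44.4 ± 9.91 and the glutamate receptor gene Gria2 at 41.6 ± 15.8 against 58.6 ± 0.752. Of 6 dentate gyrus genes 2 were higher (limma's camera, adjusted p = 0.815), of 6 CA1 genes 3 and of 8 striatal genes 4 (adjusted p = 0.909 for both). All 7 neocortical marker genes were higher (adjusted p = 0.510), with Tbr1 at 23.7 ± 1.46 against 17.2 ± 4.13 and Lamp5 at 20.5 ± 4.24 against 15.7 ± 2.11. Of the presynaptic, postsynaptic, excitatory, dentate, CA1, striatal and neocortical genes, 0 passed when adjusted over the list alone. None of the 36 gene lists passed camera, the smallest adjusted p being 0.400, and with an estimated correlation every adjusted p = 0.997.

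**Figure D2:**
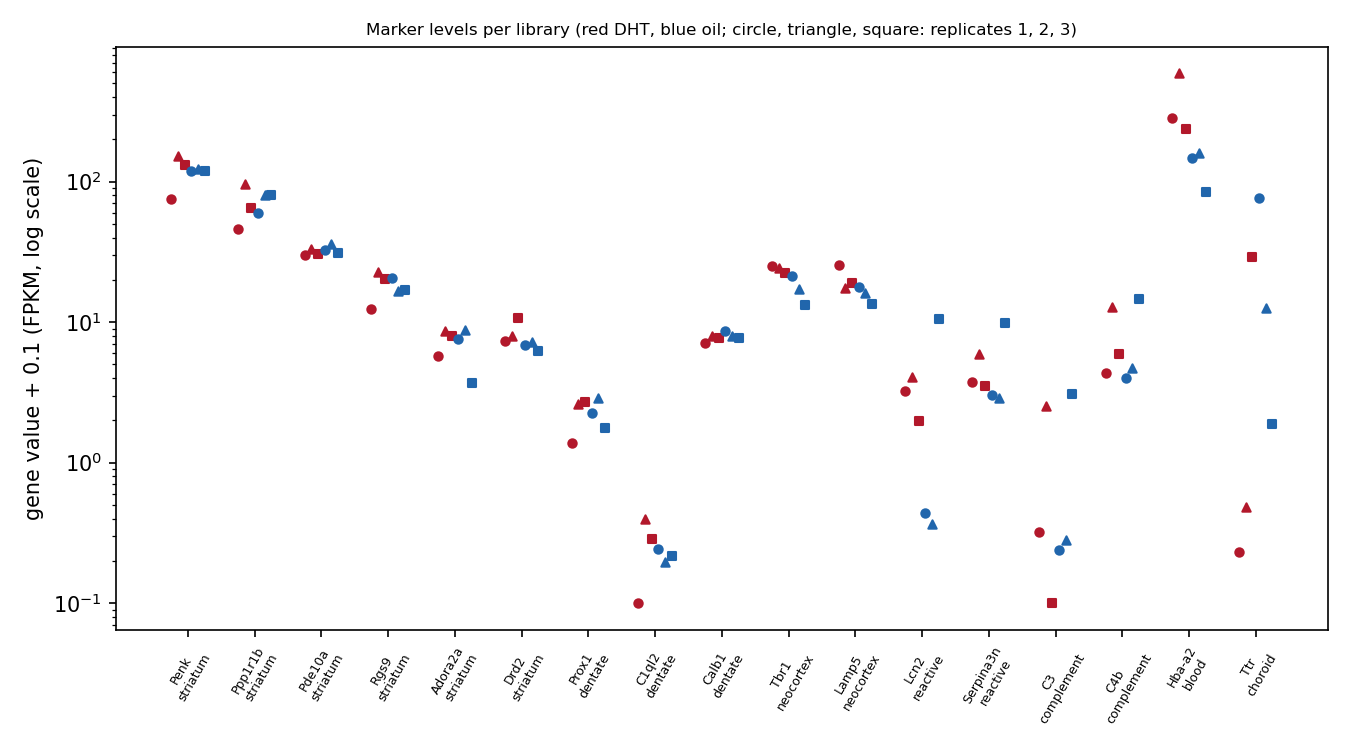
Gene values plus 0.1 in FPKM, on a log scale, for marker genes of the striatum, dentate gyrus, neocortex, reactive astrocytes, complement, blood and choroid plexus, with 1 point per library (red DHT, blue oil). DHT library 2 and oil library 3 hold the highest values of Serpina3n, C3 and C4b, and Hba-a2 does not overlap between the groups.

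The last comparison asked whether circular and linear RNA moved together. Across 2232 circRNAs with a measured host gene, the log2 fold changes of circle and host gene showed no relation past the threshold (Pearson r = 0.0212, permutation p = 0.313; Spearman correlation 0.0234, permutation p = 0.270). Without DHT library 3 the Pearson r was 0.0562 (permutation p = 0.0124). Against the linear reads at the same locus, a measure added after the data were seen, a weak positive relation passed (r = 0.0970, permutation p = 0.00016, n = 1533), as it did with 1 locus per host gene (r = 0.0928, permutation p = 0.00325, n = 1020). The first set left out loci without a single host gene, while in the second they stood for themselves, the 2 scaffold loci among them. Circles of Tmcc1, for example, were among those with the smallest p, while the linear reads at the same locus were 378, 364 and 267 in DHT libraries and 346, 338 and 283 in oil libraries. Genes whose products shape circRNA formation or stability did not move as a group: of 13 such genes 7 were higher and 6 lower (camera adjusted p = 0.815), with the helicase gene Dhx9, whose product unwinds the paired repeats that favour circle formation, at 6.67 ± 0.323 against 9.65 ± 1.53 FPKM (SD, n = 3 per group) and the RNA editing gene Adar at 15.3 ± 0.766 against 13.8 ± 0.471. No gene of this list passed over all genes (0) or adjusted over the list alone (0). These correlations are across circRNAs, which are not independent replicates.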

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

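All tests in this part, those of the linear reads with their splits and those of the scaffold locus, were chosen after the results were seen.

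The linear reads counted at circRNA loci, a measurement outside the comparisons of the report, differed between the groups for 7 loci of 1020 (edgeR, 1 locus per host gene, 113 at an unadjusted p under 0.05). Loci without a single host gene stood for themselves. DESeq2 called 6, 5 of them shared host genes, with 84 at an unadjusted p under 0.05. The 5 host genes that rose did so by both tools. Levels here are per M (mega) linear reads summed over these 1020 loci only, after TMM. Linear reads of R3hdm1 rose from 2348 ± 299 to 3398 ± 178 (SD, n = 3 per group), which is 1.45-fold (edgeR adjusted p = 0.000239). Those of Arf3, a small GTPase gene of the Golgi, rose from 13652 ± 713 to 18026 ± 678 (1.32-fold, edgeR adjusted p = 7.53e-05). Brsk2, a kinase gene of neuronal polarity, rose 1.31-fold (edgeR adjusted p = 0.0132), Elavl3, a neuronal RNA-binding gene, 1.30-fold (edgeR adjusted p = 0.0252), and the RNA-binding gene Zfr 1.28-fold (edgeR adjusted p = 0.0252). In each of these 5 genes the 3 DHT libraries lay above the 3 oil libraries. The 5 were picked by their p from the same values, so this adds no support, and 179 of all 1020 loci did not overlap.

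The gene values of the same genes, from the FPKM of exon events, were higher for Zfr (log2 fold change 0.53, SE 0.14), Arf3 (0.50, SE 0.23), R3hdm1 (0.21, SE 0.12) and Brsk2 (0.15, SE 0.10), and Elavl3 has no tested gene value. None of the 4 was past limma's threshold. For each of the 5 genes 1 circle was compared, that with the most junction reads among its circles listed in all 6 libraries. Its log2 fold change, in the fit of such circRNAs only, was 0.44 for Arf3, 0.49 for R3hdm1, 0.39 for Brsk2, -0.20 for Zfr and -0.26 for Elavl3. Other circles of a gene can differ. The Elavl3 circle described above was listed in DHT libraries only, and another R3hdm1 circle had 0, 32 and 0 reads in DHT libraries against 24, 21 and 34. Robust dispersions kept all 5, and the mean over the loci of a host gene kept 4. Leaving out DHT library 3 kept 3, oil library 1 kept 1, oil library 2 kept 2 and oil library 3 kept 2, and without DHT library 2 and oil library 3 together 1 was kept. The log2 fold changes stayed positive with 1 library left out, at 0.36 to 0.43 for Arf3, 0.46 to 0.64 for R3hdm1, 0.33 to 0.45 for Brsk2, 0.36 to 0.42 for Elavl3 and 0.33 to 0.38 for Zfr. The real split gave 7 loci, and the highest of the 9 other splits of the 6 libraries gave 1. So 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The 7 include the 2 scaffold loci weighed below, whose reads may not all be linear. Neither was called by DESeq2 (adjusted p = 0.140 for the longer and 0.350 for the shorter) or by edgeR with robust dispersions (adjusted p = 0.318 and 0.458).

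The first pattern weighed is the lower signal at the scaffold locus JH584304.1, whose 2 linear loci are the remaining 2 of the 7. Library depth is argued against, since the longer circle (25369 to 60857) was at 5.40 ± 2.90 junction reads per M mapped reads in DHT libraries and 12.4 ± 2.40 in oil libraries, a ratio of 2.29. Less back-splicing from an unchanged amount of linear RNA stays open, although the linear reads of the longer circle, at 47, 133 and 107 against 228, 264 and 355, were lower by edgeR over all loci (adjusted p = 0.000131; not by DESeq2, 0.140, or with robust dispersions, 0.318, at 1 locus per host gene; the need for both tools was set after these values were seen). These reads cannot decide it, since they were 0.892 to 1.27 times the junction reads of the shorter circle in each library, and the linear reads of the shorter circle at least 0.763 times those of the longer, so reads across the other circle's junction may have been counted as linear, and junction reads per linear read were higher in DHT libraries for the longer circle (7.96, 9.53 and 8.68 against 7.07, 7.02 and 6.57) and lower for the shorter (0.0984, 0.126 and 0.114 against 0.155, 0.154 and 0.205). Reads shared with near-identical copies stay open too. The assembled locus was at 24.7, 36.7 and 52.3 against 72.9, 79.9 and 36.6 FPKM (exact permutation p = 0.3). It was lower in DHT libraries as well (log2 fold change -0.72) and overlapped only through oil library 3, so these values cannot decide it. An effect of DHT itself stays among the open explanations, and copies cannot be told apart without a genome sequence.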

How the results depend on the processing

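Tests with other gene values, robust dispersions, circRNAs listed in all 6 libraries, linear reads in place of FPKM, 1 circRNA per host gene, list centring, estimated correlations other than in the full data, and removal of DHT library 2 and oil library 3 together (here, the pair) were chosen after the data were seen. Exceptions, both planned, were circRNAs listed in all 6 libraries for total circRNA abundance and 1 circRNA per host gene for the correlation of circular and linear changes. No paired analysis was possible because the groups share no replicate numbers in the labels.

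The 2 genes changed became 1 with a mean of at least 1 FPKM, 1 with a pseudocount of 0.1, 1 without the pair, and 0 with first-exon sums, last-exon sums or the fullest event. Leaving out 1 library gave 0 to 4. Gene lists, 0 in the report, became 1 with fry (mural), 1 with a mean of at least 0.1 FPKM (choroid plexus, lower) and 4 without the pair (glucocorticoid response, reactive astrocyte and immediate-early higher, striatum lower). Leaving out 1 library gave 0 to 2. The pair was chosen for its reactive astrocyte genes, so its removal is no test of that list or of the glucocorticoid list, which shares Lcn2. Leaving out oil library 3 alone, which held the highest Lcn2, is no test of these lists either. With an estimated correlation every list called without the pair (adjusted p = 0.778), without DHT library 2 (0.912), without oil library 3 (0.841) or at 0.1 FPKM (0.964) lost its call. Other causes were not tested.

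For circRNAs changed, 0 in the report, at least 6 reads gave 6, of which the circles of Tmeff1, Pcdh7 and Ppp1r9a each had reads in 1 library only. circRNAs listed in all 6 libraries gave 2, and leaving out 1 library 0 to 1 (a circle of R3hdm1 without DHT library 2). In the fits giving 6 and 2, edgeR gave every circRNA the shared variance, which did not occur in the other fits checked. The study's threshold, 57, became 165 with at least 6 reads and 20 with at least 60, as more or fewer circRNAs (5972 and 867) were tested. Leaving out 1 library gave 44 to 81. The 1 circRNA host list became 0 with an estimated correlation, 0 with at least 6 reads and 0 without the pair, and 0 to 1 on leaving out 1 library.

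The correlation of circular and linear changes, 0.0212, became -0.00838 with at least 60 reads and 0.0970 with linear reads (permutation p = 0.00016), and ran from -0.00200 to 0.0562 (permutation p = 0.0124, without DHT library 3) on leaving out 1 library. The 7 loci changed in linear reads became 14 with all loci and 3 without the pair, and 2 to 10 on leaving out 1 library. The difference in total circRNA abundance stayed positive, from 2.05 to 19.6 reads per M (mega) mapped reads, and that in circRNAs detected from 168 to 652, in all settings run.

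Among named genes and circRNAs, none of them past the threshold, the log2 fold change turned for Kdm5d with centring (-0.029), the fullest event (-0.19) and without the pair (-0.14), for Hbb-bs without the pair (-0.087) and with first-exon sums (-2.56). It also turned for Nlgn2 with first-exon sums (-0.57), for Cep170b (-0.20) with last-exon sums, for Dhcr7 with the fullest event (-0.066), and for the Unc79 circle without the pair (-0.23). Leaving out 1 library, it turned for Kdm5d (-0.069 to 0.15), Nr3c2 (-0.33 to 0.013), Stat2 (-0.28 to 0.000817), C1qa (-0.077 to 0.38), Psmb8 (-0.078 to 0.33), and circles of Cdr1os (-0.044 to 0.21), Unc79 (-0.10 to 0.15) and Nufip2 (-0.28 to 1.04). The causes were not tested. Counted over all single results followed, those that passed included, 24 values turned, 41 lost and 6 gained a call and 1810 kept direction and side. The 41 are of Nup98 (7), Gm22543 (6), the postsynaptic host list (6) and the 7 loci of linear reads.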

Other observations

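The tests of Nup98, of striatal markers and of the splits with an estimated correlation in this part were chosen after the results were seen, while the list tests and the counts over other splits in this part were planned.

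Cholesterol synthesis genes showed no group call (15 genes, 10 higher, camera adjusted p = 0.909), but their transcriptional regulator Srebf2 stood at 16.6 ± 4.74 against 9.44 ± 1.69 FPKM and Cyp51 at 5.12 ± 0.741 against 3.64 ± 0.596 (SD, n = 3 per group). No gene of the list passed over all genes (0) or adjusted over the list alone (0). Of 12 inhibitory neuron genes 8 were higher (camera adjusted p = 0.974), with the neuropeptide gene Npy at 26.5 ± 1.19 against 20.7 ± 1.20 and Sst at 35.6 ± 5.58 against 28.4 ± 7.23, and Gad2 at 22.3 ± 4.60 against 26.0 ± 0.447. Of 17 ribosomal protein genes 12 were higher (camera adjusted p = 0.792), with Rplp0 at 33.4 ± 2.33 against 26.1 ± 2.06, Rps29 at 21.1 ± 1.70 against 16.9 ± 1.15 and Rps27a on the lower side, the 1 gene passing when adjusted over the list alone. All 7 mural cell genes were higher (camera adjusted p = 0.671), such as the pericyte gene Pdgfrb at 3.35 ± 0.588 against 2.59 ± 0.232, and fry, which tests the list by itself and not against the other genes, gave an adjusted p = 0.0243. It was run without centring the libraries, where 63.6% of all genes were higher. The median log2 fold change of the mural genes was 0.16, and 0.098 with centred libraries.

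Of circRNAs seen in 1 library only, 5 had at least 20 reads, against a median of 3 over all 5686 of them. They were hosted by Ppp1r9a (735 reads, DHT library 1, 1.33% of its junction reads), Pcdh7 (47, DHT library 3), Tmeff1 (42, oil library 1), Nptn (29, oil library 1) and Cdr1os (20, oil library 3).

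Other splits of the 6 libraries into 3 and 3 were counted for each model. Genes changed were 2 in the real split and at most 4 in the others, with 4 of 10 splits reaching the real count. circRNAs changed were 0 and at most 1 (10 of 10), circRNAs at the study's threshold 57 and at most 62 (3 of 10), gene lists 0 and at most 7 (10 of 10), and circRNA host lists 1 and at most 0 (1 of 10). With 10 splits no share under 0.05 can be reached. The split of DHT libraries 1 and 2 with oil library 3 against the rest called 7 gene lists, and 8 of the 9 other splits called at least 1. With an estimated correlation none of the 10 splits called a list (highest 0), so these calls rest on the preset correlation of 0.01 in limma's camera, and no structure of the samples was tested.

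The second pattern weighed is the lower Nup98 value in DHT libraries, by 4.01-fold. A fall of the whole locus by that size is argued against, since its retained-intron pair had a log2 fold change of -0.19 (SE 0.11). Sums that miss transcripts are a candidate explanation, as in each DHT library another event of the locus exceeded both sums by at least 4.63 times. A first exon at 102183463 was listed at 0 in the DHT libraries and at 0, 4.17 and 3.33 FPKM in oil libraries, while oil library 1 held its signal at another first exon, 102210018 (3.88 FPKM, against 0.532 and 0.272 in the other oil libraries), so first exons moved within the oil group too. Whether DHT shifts the first exon used stays open, and the fullest event gave a log2 fold change of -0.33 (limma adjusted p = 0.659).

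The third pattern is the level of striatal marker genes in libraries from the hippocampus. Of 9 striatal genes 8 had a mean over 5 FPKM, led by Penk (75.2 to 151), Ppp1r1b (45.9 to 95.8), Pde10a (30.0 to 35.9) and Rgs9 (12.4 to 22.6), with Drd2 at 6.19 to 10.7 and Drd1 listed at 0. Of 10 dentate gyrus genes 3 had a mean over 5, Calb1 (7.75), Stxbp6 (6.72) and Pdyn (6.38), and 5 a mean under 1, such as C1ql2 (0 to 0.297), with Prox1 at 1.28 to 2.79. Striatal tissue in the libraries may account for this, although Penk, Ppp1r1b, Pde10a and Tac1 are also expressed in the hippocampus and 0 values can be failed estimates. A mix-up in single libraries is argued against, as the lowest library still had 0.652 of the median of the others. No biological explanation was tested, and the pattern is in both groups.

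Other lists gave no call in limma's camera, among them the CA2 and CA3 genes (7 of 8 higher, adjusted p = 0.701) and the circadian genes (9 of 15 higher, adjusted p = 0.994). Thalamic genes (8 of 10 higher) had an adjusted p = 0.989, oligodendrocyte genes (11 of 12 higher) 0.909 and nuclear oxidative phosphorylation genes (15 of 21 higher) 0.989. The oxidative phosphorylation genes had a median log2 fold change of 0.09 and a mean of -0.03, and Atp5e was the 1 gene passing when adjusted over the list alone.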
